A study of Mus musculus with 6 samples.

How the data were processed

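Gene expression was measured on 6 Agilent 1-colour microarrays of mouse NIH3T3 cells, an established line of embryonic fibroblasts. Per the labels' protocols, 1 population had been infected with a retroviral vector that expresses GGCT (gamma-glutamylcyclotransferase) and the other with the control vector, and both were grown with 2% serum. Total RNA was amplified and labelled with Cy3, per the labels. The groups came from the sample titles, 3 arrays each, and the titles also number the experiments 1 to 3. The design text calls the 3 experiments independent. The labels describe 1 establishment of the populations and do not say whether it was repeated, so the p-values measure the spread between these experiments.

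The scanner files hold spot intensities that were extracted with Agilent Feature Extraction 12.1.0.3, per the file headers. The headers list background subtraction and detrending within each array, and the 75th percentiles of the processed intensity differed between arrays. Each file holds 62976 spots. The 3671 control spots were left out, outlier-flagged spots were dropped (578 over the 6 arrays), and 300 probes printed in 10 spots were averaged on the log2 scale. Of 56605 probes, 35 had no usable spot on at least 1 array, which left 56570. No spot was saturated. The deposited series table holds log2 values. Each of its columns equalled the log2 processed intensity of its array minus a constant (correlation 1 over 17896 probes brighter than 200), so its scale is log2, its direction is that of the scanner files and no centring over arrays was seen. Its column medians lay between -3.88 and -3.70.

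The scanner files name probes by transcript accession and carry no gene symbols. Accessions without versions were matched to the RefSeq gene table of assembly GRCm38.p6, which named 34504 of the 56570 probes (60.99%). The remaining 22066 probes are unnamed here. The array's grid file names another genome build (mm9), so no coordinates are given, and the table served only for names and for which genes are neighbours.

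The 75th percentile of the log2 processed intensity was subtracted on each array. A gene was represented by its brightest probe over the 6 arrays and tested if that probe was well above background on all 3 arrays of at least 1 group. This kept 23774 of 44702 genes or unnamed transcripts, of which 14058 had a symbol. Called probes of 37 genes went in both directions. Differences are GGCT minus control and were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) without a block, at a Benjamini-Hochberg adjusted p under 0.05. Where a gene's probes were not well above background on any array of 1 group, the difference is a bound, given as "at least N-fold". It is the bright group's mean over the dim group's mean of, per array, the higher of the dim probe's own value and the lowest value among probes well above background. The number of arrays limits the precision of every value.

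Gene lists (25) and the rule for named genes were fixed before the data were examined. The rule names Ggct and the measured hedgehog genes, the 12 largest increases and the 12 largest decreases among called genes that moved one way in all 3 pairs, up to 4 members per list with the smallest p, and up to 6 genes per direction with the largest bounds. Examples outside the rule are said to be chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, over lists with at least 5 tested genes. A member count "adjusted over the list alone" corrects the p-values over that list's members.

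Replicate 1 of both groups was on slide 1 and in scan 1, and replicates 2 and 3 of both groups were on slide 2 and in scan 2. With slides and numbers partly overlapping, same-numbered arrays deviated together from their group means, with correlations across genes of 0.731, 0.453 and 0.358 for numbers 1, 2 and 3. The titles' numbers were therefore taken to pair the samples. On slide 2 the arrays of different numbers also correlated (0.299 and 0.342). Results with the number as a block are given where the call changed or a count moved by over 1.5 times.

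The alternatives were quantile normalization, a median shift, no filter on dim probes, a filter over all 6 arrays, the mean of a gene's probes, every probe on its own, a trended robust variance, array weights, the replicate number or the slide as a block, slide 2 alone, the deposited log2 values, and leaving out each array or each replicate number. Slide 2 alone and leaving out replicate number 1 are the same run, and both are counted among the 22 alternatives. A background correction planned on mean spot signals could not be run, since that column was not among those in the files used here. It was replaced by normexp with an offset of 50 on the median spot signals, chosen after the columns were seen. The procedure was tested on simulated data for the 23774 genes of this comparison, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. It recovered 0% of genes changed by 0.5, 56.7% of those changed by 1 and 89.4% of those changed by 2, with 7 false calls among the unchanged genes. With so few changed genes the adjusted threshold is stricter than in the data, where 34.8% of genes were called. The simulation also held no slide or pair effect, so these shares do not give the recovery in the data.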

Results

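The series compared NIH3T3 fibroblasts that stably express GGCT with cells that carry the control vector, 3 arrays against 3. GGCT is an enzyme of the gamma-glutamyl cycle, in which glutathione is broken down and its amino acids are recovered. The series title names Desert hedgehog (Dhh) and knockdown of GGCT in mouse glioblastoma stem cells. The comparison here asks which transcripts differ when GGCT is expressed in a fibroblast line. Between 54.6% and 61.7% of probes were well above background on each array, and the 75th percentile of the signal lay between 380.0 and 471 units.

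With GGCT more members of the hedgehog and mitotic lists were higher than lower, and more members of the ATF4, NRF2 and matrix lists were lower than higher. With an estimated correlation between members only the ATF4 list kept its shift (adjusted p = 0.0343, but 0.377 with the replicate number also as a block), and the hedgehog, mitotic and NRF2 lists (adjusted p = 0.338 each) and the matrix list (adjusted p = 0.342) did not. Of 23774 genes or unnamed transcripts tested, 4164 were higher and 4110 lower with GGCT, 34.8% of those tested. At least 2-fold differences were found for 862 of the higher and 1260 of the lower ones. Measured differences of at least 8-fold were more often decreases (236) than increases (46). Both fold counts include genes not well above background in 1 group, whose bounds can be smaller than the measured fold. All 8274 called genes moved one way in each of the 3 same-numbered pairs, which is no separate support, since the calls rest on the same arrays. The groups did not overlap for 49.3% of the genes tested, where chance gives 10%. With the replicate number as a block, 6490 genes were higher and 6195 lower, and with the slide as a block 6562 and 6191. Without both arrays of replicate 1, which leaves slide 2 alone, the counts were 4573 and 4539. They were 1316 and 1642 without both arrays of replicate 2, and 692 and 1089 without both arrays of replicate 3. In these last runs the arrays left span both slides and the fit had no slide term.

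Ggct itself, read by 1 mouse probe, stood at -0.57, -0.72 and -0.66 on the control arrays and at -0.14, 0.20 and -0.16 on the GGCT arrays (log2 relative to the array's 75th percentile, experiments 1 to 3). The mean difference was 0.62 ± 0.12 (SE, n = 3 against 3), a fold of 1.53 (limma, adjusted p = 0.0111). An exact 2-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The species of the expressed coding sequence is not given in the sources used here, so the mouse probe may or may not read the vector's transcript, and the value does not measure the degree of overexpression. The difference was 0.43 on slide 1 and 0.71 on slide 2. It missed the threshold without both arrays of replicate 2 (0.47, adjusted p = 0.0755), without both arrays of replicate 3 (0.67, adjusted p = 0.108) and with no filter on dim probes (adjusted p = 0.0504). Over all alternatives the adjusted p lay between 0.00233 and 0.108.

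Dhh, a secreted hedgehog ligand, rose 4.36-fold with GGCT, from -3.97 ± 0.28 in control cells to -1.85 ± 0.12 (SD, n = 3 each), a log2 difference of 2.12 ± 0.16 (SE, limma adjusted p = 0.000372). It was a dim transcript, well above background on all 6 arrays. The difference was 1.85 on slide 1 and 2.26 on slide 2, and 0.92 with normexp background, whose added offset compresses differences of dim probes. Gli1, a transcription factor and itself a target of the pathway, rose 3.05-fold (1.61 ± 0.11, adjusted p = 0.000297). Its relative Gli2 rose too (1.61 ± 0.22, adjusted p = 0.00282, and 0.72 with normexp background). Exact permutation tests gave p = 0.1 for each of these 3 genes, the smallest possible here. Dhh and Gli1 stayed past the threshold in all 22 alternatives, and Gli2 in all but the one without both arrays of replicate 2. In the same direction moved Hhat, the acyltransferase of hedgehog ligands (0.82), Gpr161 (0.65), the signal transducer Smo (0.45), the pathway inhibitor Sufu (0.41) and the ligand Ihh (1.21), whose probe was above background on 2 of the 3 control arrays. Scube2, which helps to release the ligands, fell by 1.52 on its brightest probe, by 0.66 with normexp background and by 0.73 with the mean of its probes, and another of its probes, detected on all 6 arrays, differed by 0.06. The co-receptor Cdon fell by 0.50 on the log2 scale. A further probe of Hhat differed by 0.13, and 2 further probes of Sufu by 0.47 and -0.14. With the mean of their probes Hhat differed by 0.47 and Sufu by 0.25. Hhat, Gpr161, Smo, Sufu, Ihh and Cdon each missed the threshold without both arrays of replicate 3. Smo missed it in 8 of 22 alternatives, among them the median shift and no filter on dim probes, and Cdon in 7. Sufu also missed it with the mean of its probes and with no filter, and Ihh with normexp background (0.26) and with no filter.

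The receptor and pathway target Ptch1 had a difference of 0.67 (adjusted p = 0.0552), which passed with the replicate number as a block (adjusted p = 0.0490, range over the alternatives 0.0474 to 0.161). Disp1 (0.33, adjusted p = 0.0560) and Gas1 (-0.22, adjusted p = 0.149) likewise passed with the block, at adjusted p = 0.0248 (range 0.0248 to 0.255) and 0.0354 (range 0.0354 to 0.406). Kif7 (-0.14) did not differ beyond the error. Of 15 hedgehog genes tested, 8 were higher and 2 lower, and 10 and 2 adjusted over the list alone. The list as a whole was shifted upward by camera (median 0.45, adjusted p = 0.0296). The call was lost with an estimated correlation (adjusted p = 0.338) and with the replicate number as a block (adjusted p = 0.0900, range over the alternatives 0.0163 to 0.0900). It was also lost with the slide as a block (adjusted p = 0.0705), with the mean of a gene's probes, on slide 2 alone and without replicate 3. Its median was 0.43 on each slide.

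**Figure D1:**
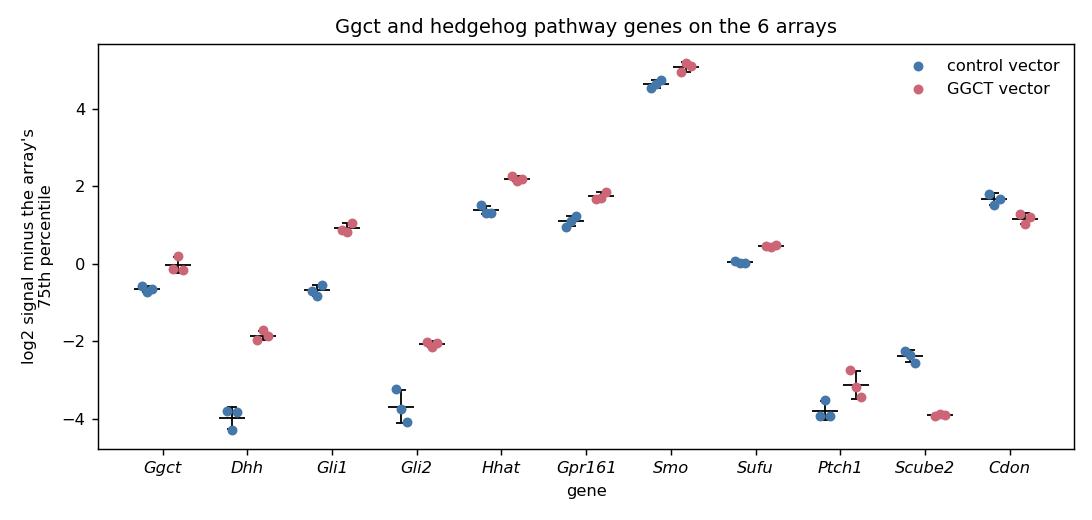
Log2 signal of Ggct and 10 hedgehog pathway genes relative to each array's 75th percentile (vertical axis), 1 point per array, with the control vector in blue and the GGCT vector in red. Horizontal bars are group means and whiskers are 1 SD (n = 3). The Dhh values rose from a mean of -3.97 to -1.85 and the Gli1 values from -0.68 to 0.93, while the Ptch1 values of the groups lie closer together (-3.79 and -3.12).

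The largest increase was that of Agtr2, the type 2 angiotensin receptor, which rose 93.0-fold (6.54 ± 0.12, adjusted p = 8.94e-06) and was above background on all arrays. Its log2 difference lay between 4.75 and 6.67 over the alternatives. Bnc1, a zinc finger protein, rose 13.8-fold (3.79 ± 0.11). Several other genes were not well above background on any control array and are given as bounds. Lin28b, an RNA-binding protein that blocks let-7 maturation, was at least 11.3-fold higher, the ubiquitin ligase Rnf43 at least 9.33-fold, the ligand Wnt10a at least 7.83-fold, Ttll2 at least 6.26-fold, the inflammatory protease Casp1 at least 5.79-fold, Aspa at least 5.39-fold, Samt1c at least 3.26-fold and Npl at least 3.14-fold. Adam22, the formin Fhod3 and the prolyl hydroxylase Egln3 were above background on 1 of the 3 control arrays and rose, with log2 differences over the alternatives from 2.14 to 6.37, from 2.54 to 5.54 and from 1.83 to 4.19. Osbp2 was above background on 2 control arrays and rose (1.78 to 4.13). In all, 160 genes were well above background on all 3 GGCT arrays and on no control array, and 143 of them were called higher.

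Decreases went further. Lama4, a laminin chain of basement membranes, was at least 159-fold lower with GGCT, the secreted protein Tafa5 at least 113-fold, the collagen-binding integrin Itga11 at least 74.95-fold and the potassium channel Kcnj2 at least 55.0-fold. The chemokine Cxcl12 was at least 35.0-fold lower, and the carboxylesterase Ces2g at least 35.0-fold. Bounds were 44.1-fold for Ctla2a, 34.5-fold for Id4, an inhibitor of basic helix-loop-helix factors, 27.6-fold for the microtubule protein Map2, 22.7-fold for the carboxylesterase Ces1f and 19.8-fold for Pxdc1. The nuclear receptor Rora fell and was above background on 1 of the 3 GGCT arrays, with log2 differences from -7.16 to -4.43 over the alternatives. The bounds rest on the processed intensities, and with normexp background the differences of genes given as bounds were smaller, for Lama4 -5.11 and for Lin28b 1.54 on the log2 scale. There were 261 genes well above background on all control arrays and on no GGCT array, of which 254 were called lower. All 24 genes named here by size, apart from Adam22, stayed past the threshold in every alternative run, and Adam22 missed it without both arrays of replicate 2 or of replicate 3.

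Genes of the ATF4 response, which covers amino acid supply and stress of the endoplasmic reticulum, were lower with GGCT. Of 28 tested, 23 fell and 0 rose, with the same counts adjusted over the list alone. Chac1, an enzyme that like GGCT takes part in glutathione breakdown, fell 6.03-fold (-2.59 ± 0.07), Trib3 4.99-fold and the folate enzyme Aldh1l2 3.58-fold, and the lipoprotein receptor Vldlr was at least 10.8-fold lower. Among members outside the naming rule, chosen after their values were seen, Atf4 itself had a difference of -0.94 and the asparagine synthetase gene Asns one of -0.82. The list was shifted downward by camera (median -0.76, adjusted p = 2.62e-11), also with an estimated correlation (adjusted p = 0.0343), but not when that was combined with the replicate number as a block (adjusted p = 0.377). Without the block the estimate was -0.0212, so that test allowed for no positive correlation between members. The list's median was -0.74 on slide 1 and -0.77 on slide 2.

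Glutathione and NRF2 genes were also more often lower than higher. Of 28 genes of the glutathione and gamma-glutamyl cycle, 15 were lower and 2 were higher, and 15 and 4 adjusted over the list alone. The peroxidase Gpx7 fell by 3.02 on the log2 scale, the transferases Gstm2 and Mgst1 by 2.81 and 2.73. The 2 that rose were Ggct and Gsto1 (0.82), the latter named after its value was seen. The list was shifted downward (median -0.41, camera adjusted p = 0.000503), a call lost with an estimated correlation (adjusted p = 0.338). With the replicate number as a block 4 members were higher and 16 lower. Its median was -0.32 on slide 1 and -0.45 on slide 2. Among 21 NRF2 targets, genes of the response to oxidants, 13 were lower and 0 higher, and 14 and 0 adjusted over the list alone. Ephx1 fell 4.73-fold, Osgin1 3.37-fold, Hmox1, the haem oxygenase, 2.61-fold and Nqo1 2.39-fold. The shift (median -0.40, camera adjusted p = 3.42e-06; -0.42 on each slide) was lost with an estimated correlation (adjusted p = 0.338).

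Mitotic genes rose almost without exception. Of 33 G2/M genes tested, 31 were higher and 0 lower, and 32 and 0 adjusted over the list alone. The spindle checkpoint kinase Bub1 rose 2.67-fold, the phosphatase Cdc25c 2.32-fold, the kinesin Cenpe 2.16-fold and Bub1b 2.03-fold. The list's median was 0.94 (0.92 on each slide, camera adjusted p = 8.98e-14), and the call was lost with an estimated correlation (adjusted p = 0.338). Of 32 genes of G1/S and DNA replication, 22 were higher and 0 lower, and 23 and 0 adjusted over the list alone. Exo1 rose 2.21-fold, Uhrf1 1.95-fold, the replication licensing factor Cdc6 1.92-fold and E2f2 1.74-fold (list median 0.57, 0.50 on slide 1 and 0.58 on slide 2, camera adjusted p = 4.97e-07). This call too was lost with an estimated correlation (adjusted p = 0.458). Among 21 p53 targets and cyclin-dependent kinase inhibitors, 9 were lower and 2 higher, and 10 and 2 adjusted over the list alone. With the replicate number as a block 12 were lower and 4 higher. Eda2r fell by 1.93 and Rrm2b by 1.15 on the log2 scale (-1.28 and -0.67 with normexp background), whereas the kinase inhibitors Cdkn1c, at least 1.92-fold higher, and Cdkn2c, 1.57-fold higher, rose. The downward shift of that list (median -0.24, -0.32 on slide 1 and -0.21 on slide 2, camera adjusted p = 0.0341) was lost with an estimated correlation (adjusted p = 0.338), with quantile normalization, with normexp background and when replicate 1 of either or both groups was left out.

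Matrix and contractile genes changed in both directions, with more decreases. Of 35 collagen and matrix genes, 18 were lower and 8 higher, the same numbers adjusted over the list alone. Postn, the matrix protein periostin, fell 58.4-fold (log2 difference -5.87, and -7.41 to -4.41 over the alternatives) and the microfibril protein Mfap5 30.5-fold. The brightest Col12a1 probe stood at -2.46 in control cells and was not well above background with GGCT, where another of its probes was on 1 array. The proteoglycan Lum rose by 1.75 on the log2 scale, and by 0.70 with normexp background. The list was shifted downward (median -0.43, -0.36 on slide 1 and -0.45 on slide 2, camera adjusted p = 0.0135), a call lost with an estimated correlation (adjusted p = 0.342). Of 22 TGF-beta and myofibroblast genes, 10 were lower and 3 higher, and 12 and 4 adjusted over the list alone. Besides Itga11, Tgfb2 fell by 2.94 on the log2 scale (-1.59 with normexp background), the myosin light chain Myl9 4.24-fold and the actin-binding Tagln 4.24-fold. The shift (median -0.37, -0.46 on slide 1 and -0.34 on slide 2, camera adjusted p = 0.00706) was lost with an estimated correlation (adjusted p = 0.338). With the replicate number as a block 14 were lower and 5 higher. Of 20 matrix proteases and their inhibitors, 8 were lower and 5 higher, also adjusted over the list alone. The inhibitor Timp1 fell 3.14-fold and the membrane protease Mmp14 2.74-fold, while Adamts4 rose 2.93-fold and Plau 1.68-fold (list median -0.39, camera adjusted p = 0.181). Timp1 lies in a run of 150 neighbouring genes with a median difference of -0.62.

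Genes of lysosomes and autophagy were lower in 14 of 30 cases and higher in 2, the same adjusted over the list alone. Lamp2 fell 1.97-fold (log2 difference -0.98, or -1.53 with every probe tested), Gabarap 1.73-fold and Lamp1 1.60-fold (list median -0.27, -0.32 on slide 1 and -0.28 on slide 2, camera adjusted p = 0.00138). The call was lost with an estimated correlation (adjusted p = 0.484). Lamp2 is in the same neighbourhood as Timp1. Of 28 genes of cholesterol and fatty acid synthesis, 8 were lower and 2 higher, the same adjusted over the list alone. Sqle fell 1.62-fold, Fdft1 1.47-fold, Srebf2 1.35-fold and Acaca 1.29-fold, the latter 2 missing the threshold in 4 and 5 of 22 alternatives, among them no filter on dim probes (adjusted p up to 0.148 and 0.191) (list median -0.20, -0.23 on slide 1 and -0.19 on slide 2, camera adjusted p = 0.0268). That call was lost with an estimated correlation (adjusted p = 0.545), with quantile normalization, with normexp background, without control replicate 1 and without both arrays of replicate 1 or of replicate 3. Of 29 genes of glycolysis and hypoxia, 11 were higher and 4 lower, also adjusted over the list alone. Besides Egln3, which rose, Pfkp fell 6.08-fold, Ero1a 3.38-fold and Vegfa 2.07-fold on its brightest probe, where 3 further Vegfa probes differed by -0.71, -0.42 and 0.08 and the mean of its probes by -0.52 (list median 0.16, camera adjusted p = 0.262, and 0.0223 with every probe tested, range over the alternatives 0.0223 to 0.390). Of 12 adipocyte genes, 5 were lower and 2 higher, the same adjusted over the list alone, with Lpl down 2.18-fold, Plin2 2.12-fold and Acsl1 1.60-fold, and Dgat2 up 1.76-fold (list median -0.39, between -0.58 and -0.04 over the alternatives, camera adjusted p = 0.166). With every probe tested the adipocyte list passed (adjusted p = 0.0135, range over the alternatives 0.0135 to 0.253).

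Interferon genes split, with 11 of 23 lower and 4 higher, and 12 and 4 adjusted over the list alone. Irf9 fell 1.64-fold and the class I antigen gene H2-K1 1.64-fold. Ifit3 fell by 1.58 on the log2 scale (-1.05 with normexp background), whereas Irf7 rose by 1.75 (0.94). The downward shift (median -0.50, -0.49 on slide 1 and -0.50 on slide 2, camera adjusted p = 0.0296) was lost with an estimated correlation (adjusted p = 0.351), without GGCT replicate 2 and with the filter over all 6 arrays. Inflammatory genes showed no shift as a list (median -0.08, camera adjusted p = 0.836), with 6 of 22 higher and 4 lower, also adjusted over the list alone. Besides Cxcl12, Cxcl5 fell 2.06-fold and Ccl7 1.59-fold, and Il11 rose 2.74-fold. Immediate early and ERK output genes went both ways, 10 of 29 higher and 9 lower, and 10 and 10 adjusted over the list alone (median 0.07, below 0 without GGCT replicate 2, camera adjusted p = 0.966). Spry1 fell 5.68-fold and Egr2 4.97-fold, while Etv1 rose 2.21-fold and Spred3 rose by 1.20 on the log2 scale (0.79 with normexp background, and 0.43 on a further probe). Of 23 Wnt genes, 5 were higher and 6 lower, and 5 and 7 adjusted over the list alone (median 0.09, below 0 with normexp background and with no filter on dim probes, camera adjusted p = 0.965). With the replicate number as a block 9 were higher and 8 lower. Besides Wnt10a, the ligand Wnt9a rose 2.18-fold, and the antagonists Sfrp1, at least 8.98-fold lower, and Dkk3, 2.77-fold lower, fell. Of 13 Notch genes, 4 were lower and 1 higher, and 4 and 2 adjusted over the list alone, or 6 and 3 with the replicate number as a block (median -0.26, above 0 with the filter over all 6 arrays, camera adjusted p = 0.414). Hes1 fell and was above background on 2 of the 3 GGCT arrays (-2.88 to -1.18 over the alternatives), Maml2 fell 2.12-fold, Lfng was at least 2.16-fold lower, and Dtx4 rose 2.04-fold.

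**Figure D2:**
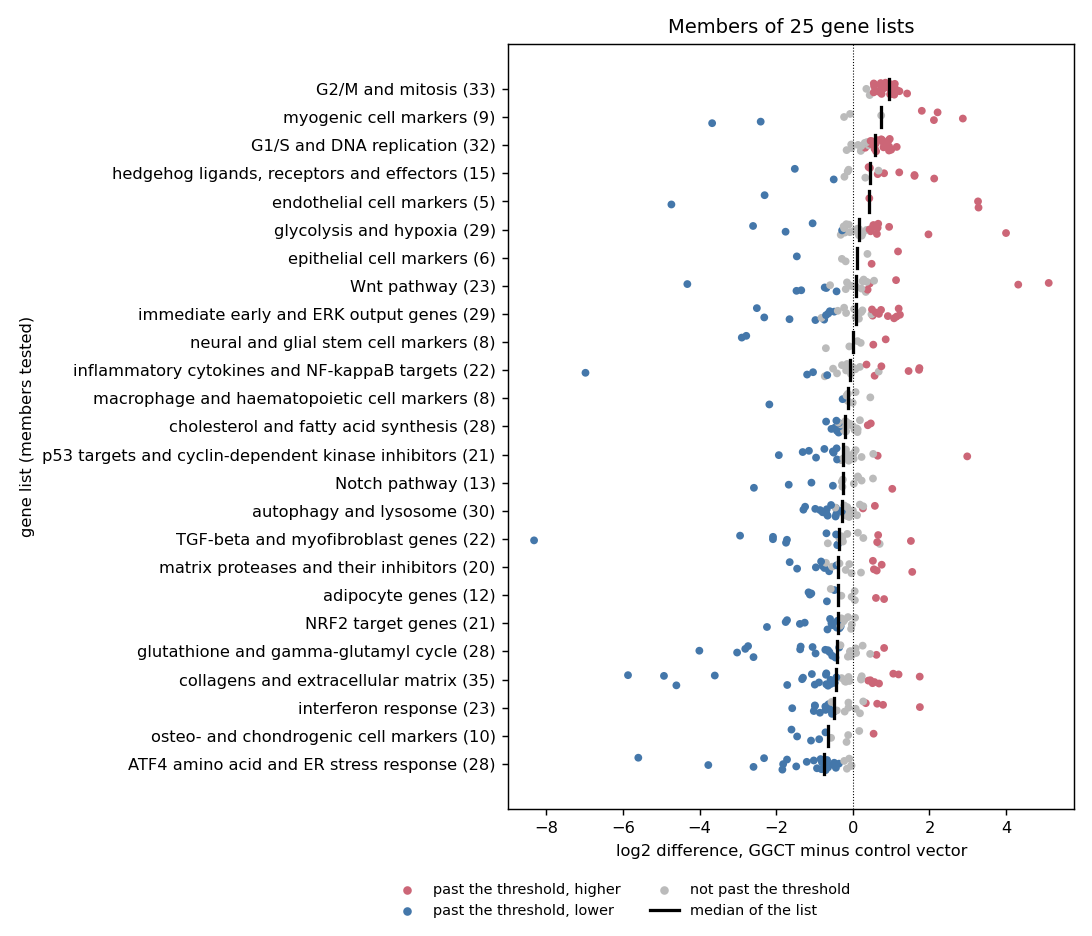
Log2 differences (GGCT minus control vector, horizontal axis) of the tested members of 25 gene lists, with the number tested in brackets. Points are genes, red for called higher, blue for called lower and grey for not past the threshold, as measured and without bounds, and black bars are medians. G2/M genes lie to the right (median 0.94) and ATF4 response genes to the left (median -0.76), while most other lists hold genes on both sides.

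Markers of other cell types moved in both directions. Of 5 endothelial genes tested, 3 were higher and 2 lower, the same adjusted over the list alone. Flt1, above background on 2 control arrays, rose (1.37 to 3.45 over the alternatives) and Cdh5 was at least 2.18-fold higher, but Egfl7, above background on 1 GGCT array, fell (-5.05 to -2.09) and Vwf was at least 1.44-fold lower (median 0.43, camera adjusted p = 0.618). Of 9 myogenic genes, 4 were higher and 2 lower, also adjusted over the list alone (median 0.74, or 0.55 with genes at their bounds -0.23 with the filter over all 6 arrays and below 0 with no filter on dim probes, camera adjusted p = 0.598). Acta1 fell 12.8-fold and Actc1 5.30-fold, Myh1 was at least 1.46-fold higher but not past the threshold with normexp background (0.31, adjusted p = 0.0534, range over the alternatives 9.27e-05 to 0.0534), and Tnnt1, above background on 1 control array, rose (0.62 to 2.61 over the alternatives). Of 10 osteo- and chondrogenic genes, 5 were lower and 1 higher, and 6 and 1 adjusted over the list alone. Spp1, the secreted osteopontin, fell 3.04-fold, Col10a1 1.84-fold (log2 difference -0.88, or -0.56 with normexp background) and Sox9 1.64-fold, which missed the threshold in 5 of 22 alternatives, among them no filter on dim probes, and Runx2 rose 1.46-fold on its brightest probe. Another Runx2 probe detected on all arrays differed by 0.13, and the call was lost with the mean of its probes (adjusted p = 0.245, range over the alternatives 0.000962 to 0.245) and without replicate 2 or 3. That list was shifted downward (median -0.64, -0.69 on slide 1 and -0.62 on slide 2, camera adjusted p = 0.0444), a call lost with an estimated correlation (adjusted p = 0.338) and with the replicate number as a block (adjusted p = 0.0735, range over the alternatives 0.0247 to 0.151). It was lost in 9 further alternatives, among them normexp background, the slide as a block (adjusted p = 0.0612) and no filter on dim probes. Of 8 macrophage genes, 2 were lower and 0 higher, and 1 and 0 adjusted over the list alone, with 1 higher under the replicate block (median -0.13, camera adjusted p = 0.371). Aif1 fell 4.53-fold. Cd68 fell 1.20-fold (adjusted p = 0.0451) but missed the threshold in 15 of 22 alternatives (range 0.0185 to 0.248), and Csf1r (0.46, adjusted p = 0.311) and Fcer1g (-0.16) were not past the threshold. With the replicate number as a block Csf1r passed (adjusted p = 0.0128, range over the alternatives 0.0128 to 0.643). Of 6 epithelial genes, 2 were higher and 1 lower, also adjusted over the list alone (median 0.10, below 0 in 5 alternatives, namely normexp background, no filter on dim probes, the filter over all 6 arrays and without control replicate 3 or both arrays of replicate 3, camera adjusted p = 0.864). Cldn4 rose 1.40-fold but missed the threshold in 6 of 22 alternatives, among them no filter on dim probes (adjusted p up to 0.149), Krt8 rose by 1.18 on the log2 scale (0.57 with normexp background), Krt14 fell by 1.46 (-0.63) and Krt7 was not past the threshold (0.38). Krt7 passed with array weights (adjusted p = 0.0346, range over the alternatives 0.0346 to 0.97). Of 8 neural and glial genes, 2 were higher and 2 lower, the same adjusted over the list alone (median 0.01, camera adjusted p = 0.694). The median was below 0 in 8 alternatives. These were normexp background, a median shift, no filter on dim probes, and those without control replicate 1, control replicate 3, GGCT replicate 2, GGCT replicate 3 or both arrays of replicate 3. The glutamate transporter Slc1a3 fell 6.88-fold, S100b was at least 2.85-fold lower, and Pdgfra rose 1.81-fold and Gfap 1.45-fold, the latter not past the threshold with normexp background (0.16).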

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

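The normexp background was chosen after the file columns were seen. All other alternatives were set before the data were examined, and normexp on mean spot signals was not run for want of that column. The counts of higher and lower genes were 2218 and 2493 with no filter on dim probes, 6633 and 6193 with array weights, 6490 and 6195 with the replicate block, 6562 and 6191 with the slide block, and 862 and 1260 at a minimum of 2-fold. Leaving out arrays or replicates gave 692 to 4573 higher and 1089 to 4539 lower genes, lowest without replicate 3. The causes of these changes were not tested. Of the 8274 calls, 86.4% kept their sign and side of the threshold with normexp background. The shares were 96.05% with quantile normalization and 89.6% with a median shift. By these shares the scaling or background step does not account for most calls. The deposited log2 values kept 99.8%, which adds nothing here, since they have the same background and scaling as the main run. The share of higher genes among calls, 50.3%, lay between 46.3% and 52.6% under these scalings, and 14 calls turned sign with normexp. Without replicate 3 20.4% of the calls were kept, without replicate 2 34.9% and without replicate 1, on slide 2 alone, 89.2%. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave 8274 called genes, and the highest of the others gave 0, as did the other 3 splits that part all pairs. With 10 splits no share under 0.05 can arise. Each other split puts GGCT and control arrays on both sides, so the group difference adds to its spread. The 0 calls there do not measure how many calls arise without a group difference. Camera called 13 of 25 lists, 1 with an estimated correlation (the ATF4 list), 0 when the replicate block was added to that, and 20 were called by fry, which does not compare a list with other genes. A call lost with an estimated correlation need not reflect correlated members, since the osteo- and chondrogenic list lost its call at an estimate of -0.0622. Nor does the ATF4 call, kept at an estimate of -0.0212, show that it withstands correlated members. Leaving out arrays or replicates gave 9 to 13 lists. Ggct kept its direction throughout, with 0.62 and an adjusted p of 0.0504 with no filter on dim probes, which tests more genes, and 0.47 to 0.71 when arrays or replicates were left out. Dhh passed everywhere, between 0.92 and 2.26. For the 131 other named genes, 2733 of 2843 comparisons kept the direction and the side of the threshold, 99 lost the threshold (80 of them with fewer arrays), 11 gained it and 0 reversed. Of 125 called named genes 84 passed in every alternative that tested them, and 39 missed the threshold without replicate 3. The filter over all 6 arrays did not test all of them. The replicate block changed no other call among named genes and lists than those given beside the results. Probes below background on either side limit what can be said of dim genes.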

Other observations

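Chosen after results were seen were the gene families, the admixture and dim-probe tests, the stretch of neighbouring genes, the interval of the dosage share and the reading of the replacement test. The families were picked for their members' values, so only counts are given and no test. Homeobox genes of the HOX clusters were higher in 12 of 22 cases and lower in 2. Hoxd3 rose by 1.24, Hoxa4 by 0.96 and Hoxd4 by 0.95 on the log2 scale, but Hoxb9 fell and was above background on 1 GGCT array. Integrins, with the integrin-like gene Itgbl1 counted among them, were lower in 12 of 19 cases and higher in 2. Itga11 and Itga9 were on no GGCT array above background, and Itgbl1 fell by 5.82 and Itgb4 by 2.69, whereas Itga3 rose by 2.08 and Itga7 by 0.65. Of 6 laminins 3 were lower and 0 higher. Of 5 carboxylesterases Ces1a, Ces1f, Ces1g and Ces2g were lower and above background on no GGCT array.

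Imprinted growth genes included Peg3 (1.94), Igf2 (1.56) and Plagl1 (1.42) among 5 of 12 that rose, and Slc38a4 (-0.80) as the 1 that fell. Cytosolic ribosomal proteins were lower in 6 of 48 cases and higher in 0 (median -0.20). Of 54 subunits of the respiratory chain 4 were higher and 6 lower (median -0.01).

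The mouse Ggct probe may not read the vector's transcript, so its rise does not measure the degree of overexpression. A large share of genes passed the threshold (8274) while that probe rose 1.53-fold, and 4628 called genes had a larger difference than Ggct. The slides or scans do not account for this, since the differences measured on each slide, which share no array, correlated across genes with a Spearman coefficient of 0.871 (bootstrap interval 0.867 to 0.877, genes not being independent). Dosage differences of chromosome segments may contribute, since medians of runs of 50 neighbouring genes spread more (SD 0.18) than in any of 1000 shuffles (at most 0.08, permutation p = 0.001, the smallest they can give), and after subtraction of each run's median 82.4% of the 1476 named genes with at least 2-fold differences kept one (94.0% with shuffled genes). The interval of that share, 79.8 to 84.8%, straddles the 80% set beforehand and leaves dosage open; a binomial interval computed first had its lower end just above 80% and would have argued against dosage, but it was replaced after that was seen by resampling whole runs, because neighbours are not independent. Other lasting differences between the populations, such as founder cells or insertion sites, could equally produce the changes, and the labels name 1 establishment of the cells, so no array here separates them from an effect of GGCT.

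The 3 runs with the lowest medians were adjacent, from Vamp7 to Ints6l, a stretch of X-linked genes. Of its 150 tested genes 96 were lower (64.0%, against 22.1% of all named genes) and 6 higher, with a median of -0.62 (-0.60 on slide 1 and -0.61 on slide 2). Agtr2, the gene with the largest increase, lies within this stretch.

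At or above the array's 75th percentile in control cells, 11 genes were on no GGCT array above background, Lama4 and Tafa5 among them. Admixture of another cell type to the GGCT cultures stays open, since no test here decides it. The 10 genes with bounds of at least 32-fold follow nearly by construction from how these genes were picked, and most lists of other cell types hold members that moved both ways. For replacement by another cell line, 0 of 24 readings of Cdkn2a and Cdkn2b, a locus lost in NIH3T3, were well above background, and 0 of the readings of 7 Y-linked probes. By the rule set beforehand this absence excluded replacement, but that reading was withdrawn after the value was seen, because another line may lack the locus too and a shared absence cannot separate the groups, so replacement stays open.

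The rise of Dhh, Gli1 and Gli2 could come from a general upward shift of dim probes. Among the 500 tested genes nearest in control level they lay at percentiles 99.8, 99.2 and 98.8. They were taken for this test after their rises were seen, so high percentiles nearly follow from that choice and decide nothing. The median log2 differences of the matched genes were 0.09, 0.04 and 0.03, against 2.12, 1.61 and 1.61 for Dhh, Gli1 and Gli2. Medians this small argue against a general upward shift at these control levels. An effect of GGCT on the pathway remains a hypothesis, since a lasting difference between the 2 populations would give the same values.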
